A study of Mus musculus with 8 samples.

How the data were processed

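RNA from whole mouse liver was sequenced in 8 libraries, 2 from each of 4 groups. The mice carried floxed alleles of b-PDGFR, the beta receptor for platelet-derived growth factor (gene Pdgfrb), and were negative or positive for Cre driven by the GFAP promoter, which the labels give as a deletion specific to hepatic stellate cells. Livers were taken after a sham operation or 72 h after partial hepatectomy, from animals of the strain 129S4/SvJae/FVB at 3 months of age. RNA was extracted with Trizol and a column step with DNase, and libraries were made with the TruSeq kit and sequenced on a HiSeq2000, per the labels' protocols. Each sample was assigned to its group from its title. The labels describe duplicates and do not say whether each library came from its own animal. P-values of single genes therefore measure only the spread between these samples.

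The deposited values are a normalized signal per gene and per isoform, for 34465 genes and 96792 isoforms in each library. TopHat, Cufflinks and the mouse builds mm9 and NCBIM37 are named in the submitters' processing notes. Their versions are not given, and the normalization is not given in the sources used here. The values are not counts and do not behave as plain FPKM: each library sums to between 8617660 and 11583800. A gene's value equalled the sum of its isoforms to within 7.4e-05. FPKM had been assumed when the tests were fixed, and the same test, limma on log values, was kept for the signal values. Whole reads could not be recovered, so the depth of each library is unknown, no counting interval or detection floor is given, and tests that need read counts were not run. No column belonged to a sample outside the 8.

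An exact 0 in these values can be a failed estimate. Alb, the albumin gene and among the most abundant transcripts of liver, was listed at 0 in 7 of the 8 libraries. In all, 105 genes were listed at 0 in a library and at 100 or more in another. Such genes are given as library values, with no fold change against a group listed at 0. Reads from near-identical paralogs (Cyp3a16 and Cyp3a44, Cyp3a41a and Cyp3a41b, Cyp4a12a and Cyp4a12b, Hba-a2, Serpina1e and the Mup cluster) may have been shared between copies, and their values are uncertain. The labels do not say whether the libraries kept strand.

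Tests were run with limma 3.58.1 in R 4.3.3 on log2(signal + 1), so that a log2 fold change understates the change of genes with low signal. Genes with a mean signal of at least 1 over the 8 libraries were tested, which left 16443. One linear model with a mean for each of the 4 groups was fitted, with a spread shared between groups and moderated along an intensity trend (residual degrees of freedom 4, prior degrees of freedom 3.25). All tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The contrasts were hepatectomy against sham within each genotype and averaged over both, Cre-positive against Cre-negative within sham, within hepatectomy and averaged over both, and the difference of the hepatectomy response between genotypes. Errors of fold changes are standard errors (SE) from this model, with n = 2 libraries per group throughout.

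A total of 38 gene lists, 12 of them cell type or sex markers, were fixed before the data were examined, as were the contrasts, the test, the rule for named genes and most of the other settings tried. Each list was tested with camera, which compares its members with all other genes, at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry. Adjusted p-values of lists were taken over the 38 lists within a contrast, and members past the threshold were counted over all genes and adjusted over the list alone. The direction of a camera result is relative to the other genes. At the preset correlation, camera p-values rest mainly on the spread across genes, with members taken as nearly independent. They do not measure the spread between libraries, and a small one can come from few libraries. No list passed camera with an estimated correlation in any contrast: the lowest adjusted p was 0.221 for hepatectomy in Cre-negative livers, 0.11 in Cre-positive livers, 0.182 averaged over both, 0.649 for genotype in sham, 0.517 in hepatectomy, 0.459 averaged over both and 0.497 for the difference of responses. With 2 libraries per group that correlation is itself poorly estimated. By fry, 9 lists passed for hepatectomy in Cre-negative livers, 3 in Cre-positive livers and 9 averaged over both. For genotype 0 passed in sham, 1 in hepatectomy and 1 averaged over both, and 1 passed for the difference of responses.

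The text names Pdgfrb in each contrast, the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose replicates do not overlap, and, for each list, up to 4 members past the threshold with the smallest adjusted p or otherwise up to 2 members of the highest mean as values. Where fewer than 5 genes passed, the 10 with the smallest p were named as not passing. Predicted genes, small RNA genes and pseudogenes were counted and not named, apart from those said to have been chosen after their values were seen. Not every gene the rule selects is printed.

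The procedure was tested on simulated data drawn with the observed spreads, in which 67 genes changed by 1, 67 by 2 and 66 by 3 on the log2 scale. Noise was drawn independently for each gene, with no trend by GC content. Shares and false calls from it hold for independent genes, and real genes may vary together. At a change of 2 it recovered 29.9% of genes for hepatectomy in Cre-negative livers, 40.3% in Cre-positive livers, 31.3% for genotype in either treatment, and 74.6% and 71.6% for the averaged contrasts. For the difference of responses it recovered 0% at a change of 2 and 9.1% at 3. Unchanged genes were called too: 3 and 8 for hepatectomy in Cre-negative and Cre-positive livers, 22 for genotype after hepatectomy, and 7 and 11 in the averaged contrasts of hepatectomy and genotype. With one spread for all groups these numbers were 8, 4, 1, 6 and 6. With the observed spreads, the share of unchanged genes at an unadjusted p under 0.05 differed between contrasts. It was 3.5% and 8.2% for hepatectomy in Cre-negative and Cre-positive livers, and 0.8% and 11.7% for genotype in sham and after hepatectomy. For the difference of responses it was 5.5%, and in both averaged contrasts 5.6%.

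Settings fixed beforehand were a pseudocount of 0.1 or 0.5, no filter, a mean of at least 5, median-of-ratios scaling, quantile normalization, only the groups compared, no intensity trend, a robust prior, and each library left out in turn. Another 3 were chosen after seeing the data: leaving out the 105 genes, array weights, and a correction for GC content. With 1 library left out, its group adds nothing to the shared spread. A larger count in such a fit is therefore no support for a call. GC content came from the GENCODE M21 annotation of GRCm38 by gene symbol, for 14566 of the 16443 genes (88.6%). That build differs from the one in the submitters' notes, so no coordinates are printed. Plots were drawn with Matplotlib 3.10.9 in Python 3.11.15.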

Results

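Gene expression was measured by RNA sequencing of whole liver in 8 libraries from mice with floxed Pdgfrb alleles, 2 each from Cre-negative sham, Cre-positive sham, Cre-negative hepatectomy and Cre-positive hepatectomy livers. The hepatectomy livers were sampled 72 h after part of the organ had been removed, during regrowth. Gene signal summed to between 10115900 and 10262000 in the sham libraries, to 8617660 and 9402630 in the Cre-negative hepatectomy libraries and to 10402100 and 11583800 in the Cre-positive hepatectomy libraries. These sums are of normalized values, and the sequencing depth behind them is unknown. Between 14881 and 17398 genes reached a signal of 1 in a library. The 10 most abundant genes held between 14.3% and 18.4% of the signal in the other libraries and 30% in Cre-positive hepatectomy replicate 2.

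Sham libraries resembled each other more than hepatectomy libraries did. The median ratio between replicates was 1.156 in Cre-negative sham, 1.15 in Cre-positive sham, 1.366 in Cre-negative hepatectomy and 1.606 in Cre-positive hepatectomy livers. Exactly equal values occurred in at most 0.05% of the genes above 0 in either replicate, so no library was a copy of its replicate. This was not counted between groups, where some values recurred. The mitochondrial gene mt-Co2, chosen after its values were seen, was at 48193 in both Cre-negative sham libraries. It was at 48193 too in Cre-positive sham replicate 1 and Cre-negative hepatectomy replicate 2. Why values recur was not tested. On the first principal component, which held 41.2% of the variance, the sham libraries lay between -52.5 and -49.7, the Cre-negative hepatectomy libraries at 89.8 and 48.8, and the Cre-positive hepatectomy libraries at -25.3 and 91.5. Cre-positive hepatectomy replicate 2 followed GC content: against the mean of the sham libraries, its median log2 difference was -1.5 over 847 genes under 40% GC and 0.664 over 3233 genes of 55% GC or more. For the GC-rich class the difference was 0.608 and 0.391 in the Cre-negative hepatectomy libraries and -0.11 in Cre-positive hepatectomy replicate 1. Transcript length had a trend too. The Spearman correlation of length with a library's deviation from the other libraries lay between 0.068 and 0.212 in sham libraries. In hepatectomy libraries it lay between -0.176 and 0.064. No correction for length was made, and its bearing on the gene lists, ribosomal proteins included, was not tested.

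**Figure D1:**
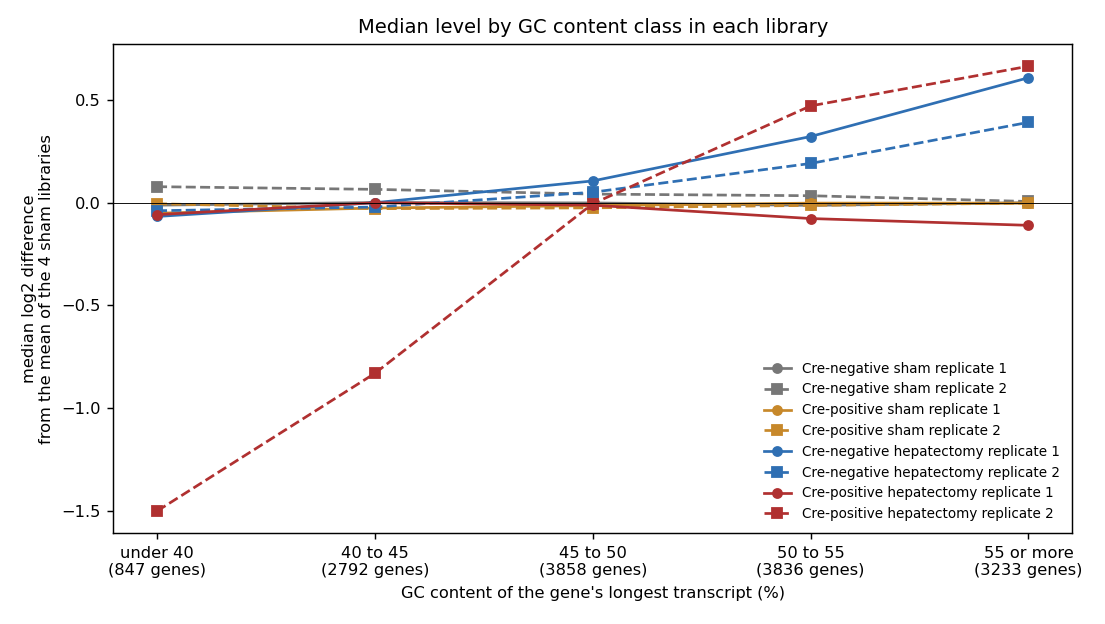
Median log2 difference of each library from the mean of the 4 sham libraries (vertical axis) by class of gene GC content in percent (horizontal axis), 1 line per library. Cre-positive hepatectomy replicate 2 climbs from -1.5 in the class under 40% GC to 0.664 in the class of 55% or more.

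The targeted gene was examined first. Pdgfrb, the receptor whose deletion the labels describe, was at a signal of 49.8 and 63.3 in the Cre-negative sham libraries and 59.4 and 46.0 in the Cre-positive sham libraries. After hepatectomy it was at 122.7 and 70.5 in Cre-negative and 63.1 and 99.9 in Cre-positive libraries. Group means were 56.5 ± 9.54, 52.7 ± 9.53, 96.6 ± 36.9 and 81.5 ± 26.0 (SD, n = 2) in the same order. The log2 fold change of Cre-positive against Cre-negative livers was -0.10 (95% interval -1.01 to 0.81, adjusted p = 1) in sham and -0.23 (-1.13 to 0.68, adjusted p = 0.769) after hepatectomy. No lower level was detected in the livers labelled Cre-positive. Whole liver holds other cells that express Pdgfrb, and the floxed part of the gene is not given in the sources used here. These values neither show nor exclude a deletion in stellate cells, and the genotype is taken from the labels. Hepatectomy against sham gave 0.72 (SE 0.39, adjusted p = 0.322) in Cre-negative and 0.59 (adjusted p = 0.521) in Cre-positive livers, neither past the threshold. Gfap, whose promoter drives the Cre, was at 3.57, 2.92, 7.35 and 4.66 in the Cre-negative and 0.75, 1.04, 0.19 and 3.04 in the Cre-positive libraries, sham before hepatectomy. The averaged log2 fold change of Gfap between genotypes was -1.41 and did not pass (adjusted p = 0.509).

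The median log2 fold change of all tested genes was not 0 in every contrast, and it moved with the scaling. It was 0.21 for hepatectomy in Cre-negative livers, and median-of-ratios scaling or quantile normalization took it to -0.002 or -0.045. Averaged over genotypes it was 0.12 and went to -0.03 with either. For Cre-positive against Cre-negative livers after hepatectomy it was -0.23 and went to -0.08 or 0.03, for the difference of responses -0.20 and went to -0.07 or 0.04, and for the averaged genotype contrast -0.13 and went to -0.03 or 0.02. Fold changes in these contrasts are to be read against those medians, as the camera tests of lists do.

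The response of control livers was given by hepatectomy against sham in Cre-negative mice. Genes of cell division rose. All 40 measured genes of the G2 and mitosis list had a positive log2 fold change, with a median of 4.04. Of these, 20 rose over all genes and 40 adjusted over the list alone. Among them, Ttk, a kinase of the spindle checkpoint, rose by 5.23 on the log2 scale (SE 0.49, adjusted p = 0.0203). Birc5, the inhibitor of apoptosis survivin, rose by 5.00 (SE 0.71, adjusted p = 0.0336) and Kif4, a chromosome-bound kinesin, by 4.16 (SE 0.44, adjusted p = 0.0203). Cdkn3 and Pbk, which also act in mitosis, rose by 5.17 (SE 0.41, adjusted p = 0.018) and 5.12 (SE 0.54, adjusted p = 0.0203). Of the 29 genes of DNA replication and S phase, 28 had a positive fold change (median 1.93). Over all genes 7 rose, and 22 rose and 1 fell adjusted over the list alone. Mcm5 and Mcm6, subunits of the replicative helicase, rose by 3.07 (SE 0.29, adjusted p = 0.0203) and 3.86 (SE 0.50, adjusted p = 0.0289), and E2f1, a transcription factor of the entry into S phase, by 2.31 (SE 0.33, adjusted p = 0.0334). Camera gave adjusted p = 8.54e-28 for the mitosis list and 4.59e-12 for the replication list, each with adjusted p = 0.221 with an estimated correlation.

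Fewer genes fell in the same contrast. Hsd3b5 and Cyp4a12a, which are expressed more in male than in female liver, fell by 2.78 (SE 0.35, adjusted p = 0.0244) and 2.40 (SE 0.28, adjusted p = 0.0244). In all, 4 of the 14 male-biased genes fell over all genes and 8 adjusted over the list alone (median -1.91, camera adjusted p = 1.55e-09). Glul, the glutamine synthetase of hepatocytes around the central vein, fell by 1.82 (SE 0.21, adjusted p = 0.0235). Pklr, the pyruvate kinase of liver, fell by 2.12 (SE 0.26, adjusted p = 0.0244), and Rgs16, a regulator of G protein signalling, by 2.83 (SE 0.39, adjusted p = 0.033). Serpina1e and Serpina3k, which encode secreted protease inhibitors, fell by 4.12 (SE 0.49, adjusted p = 0.0244) and 3.14 (SE 0.46, adjusted p = 0.0356). Camera placed the drug-metabolizing cytochromes P450 (median -0.80, adjusted p = 2.19e-08), pericentral genes (-0.72, 1.46e-05), periportal genes (-0.71, 1.82e-05), genes of bile acid synthesis and transport (-0.88, 2.79e-05) and endothelial markers (-0.85, 1.55e-07) below other genes. For the male-biased, P450, pericentral and bile acid lists this was adjusted p = 0.221 with an estimated correlation, and for periportal and endothelial genes adjusted p = 0.255 and adjusted p = 0.449 with an estimated correlation. Of the 22 P450 genes 0 fell over all genes by limma (11 fell at an unadjusted p under 0.05) and 7 adjusted over the list alone.

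Against these falls, Cyp4a14, a fatty acid hydroxylase induced through PPAR-alpha, rose by 5.48 (SE 0.67, adjusted p = 0.0244), from 44.2 and 11.1 to 730.6 and 1477.8. Acot2, a mitochondrial thioesterase of the same pathway, rose by 2.93 (SE 0.49, adjusted p = 0.0477), while the PPAR-alpha list as a whole did not pass (median 0.06, camera adjusted p = 0.779). Tff3, a trefoil peptide on the fetal liver list, rose by 3.67 (SE 0.40, adjusted p = 0.0203). Ribosomal protein genes were above other genes: 78 of 81 had a positive fold change with a median of 0.52 against 0.21 for all genes (camera adjusted p = 2.19e-08, and adjusted p = 0.221 with an estimated correlation). Of these, 1 rose over all genes, Rpl41 by 1.61 (SE 0.22, adjusted p = 0.031), and 14 adjusted over the list alone.

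In all, 166 genes rose and 17 fell in Cre-negative livers, with 3509 at an unadjusted p under 0.05. The total of 183 was 1 without Cre-negative sham replicate 1 and 0 without Cre-negative sham replicate 2 (1745 at an unadjusted p under 0.05). It was 2 without either Cre-positive sham library, 1 without Cre-negative hepatectomy replicate 1 and 45 without replicate 2. Without Cre-positive hepatectomy replicate 1 or 2 it was 1698 or 1641, with all 183 genes among them both times and 1184 or 1152 of them rising.

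The same contrast in Cre-positive livers gave the response in livers labelled as carrying the deletion. All 40 genes of the G2 and mitosis list had positive fold changes here too (median 4.2), 24 of them rising over all genes and 40 adjusted over the list alone. Ccnb1 and Ccnb2, the cyclins of entry into mitosis, rose by 5.58 (SE 0.91, adjusted p = 0.0481) and 5.26 (SE 0.70, adjusted p = 0.0279), and Top2a, the topoisomerase that separates chromosomes, by 4.66 (SE 0.55, adjusted p = 0.0188). Of the 29 replication genes, 26 had positive fold changes (median 2.15), 15 rose over all genes and 23 adjusted over the list alone. Among them, Mcm5 rose by 3.94 (SE 0.29, adjusted p = 0.00733) and Mcm2 by 3.31 (SE 0.30, adjusted p = 0.0136). Ccnd1, the cyclin D1 gene that acts before S phase, rose by 3.62 (SE 0.53, adjusted p = 0.0356). Camera gave adjusted p = 2.9e-41 for mitosis and 9.6e-24 for replication, which became adjusted p = 0.462 and adjusted p = 0.11 with an estimated correlation.

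Igfbp1, a secreted binding protein for insulin-like growth factors, fell by 3.27 (SE 0.24, adjusted p = 0.00733) in Cre-positive livers, from 5191.7 and 3787.7 in sham to 436.5 and 480.3. Gpcpd1, a glycerophosphocholine phosphodiesterase, fell by 4.77 (SE 0.72, adjusted p = 0.0403), Rgs16 by 3.93 (SE 0.39, adjusted p = 0.0176) and Hsd3b5 by 2.12 (SE 0.35, adjusted p = 0.049). Bst2, an interferon-induced antiviral gene, rose by 1.82 (SE 0.30, adjusted p = 0.049). All 26 genes of the interferon list had positive fold changes (median 1.27), with 1 rising over all genes and 10 adjusted over the list alone. Camera gave adjusted p = 2.14e-07 for that list, adjusted p = 0.534 with an estimated correlation. It gave 0.353 without Cre-positive hepatectomy replicate 1. P450 genes lay below other genes (median -0.57, camera adjusted p = 0.000302) and ribosomal protein genes above them (median 0.35, 1.64e-06, 70 of 81 positive). Both had adjusted p = 0.534 with an estimated correlation. Beside these groups stands the GC trend of Cre-positive hepatectomy replicate 2, in which genes under 40% GC were lower by a median log2 difference of -1.5.

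In Cre-positive livers 139 genes rose and 16 fell, with 2219 at an unadjusted p under 0.05. The total of 155 was 9, 10, 1 and 5 without Cre-negative sham replicate 1 or 2 or Cre-positive sham replicate 1 or 2. It was 75 and 62 without Cre-negative hepatectomy replicate 1 or 2, 143 without Cre-positive hepatectomy replicate 2, with 66 of the 155 among them, and 3507 without Cre-positive hepatectomy replicate 1, with all 155 genes among the last. Of those 3507 genes 1464 rose and 2043 fell. With only the Cre-positive groups in the limma fit it was 0 (1493 at an unadjusted p under 0.05).

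Both genotypes shared 88 genes that rose, where independent lists would share 1.4, and 3 that fell, where they would share 0.02. The contrasts share no library, but both take their spread from all 8 libraries, so the values for independent lists are not those of no change. Of the 166 genes that rose in Cre-negative livers, 150 had a positive fold change in Cre-positive livers, and of the 139 that rose in Cre-positive livers, 138 had a positive one in Cre-negative livers. Across the 16443 genes, which are not independent replicates, the fold changes correlated with r = 0.461.

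**Figure D2:**
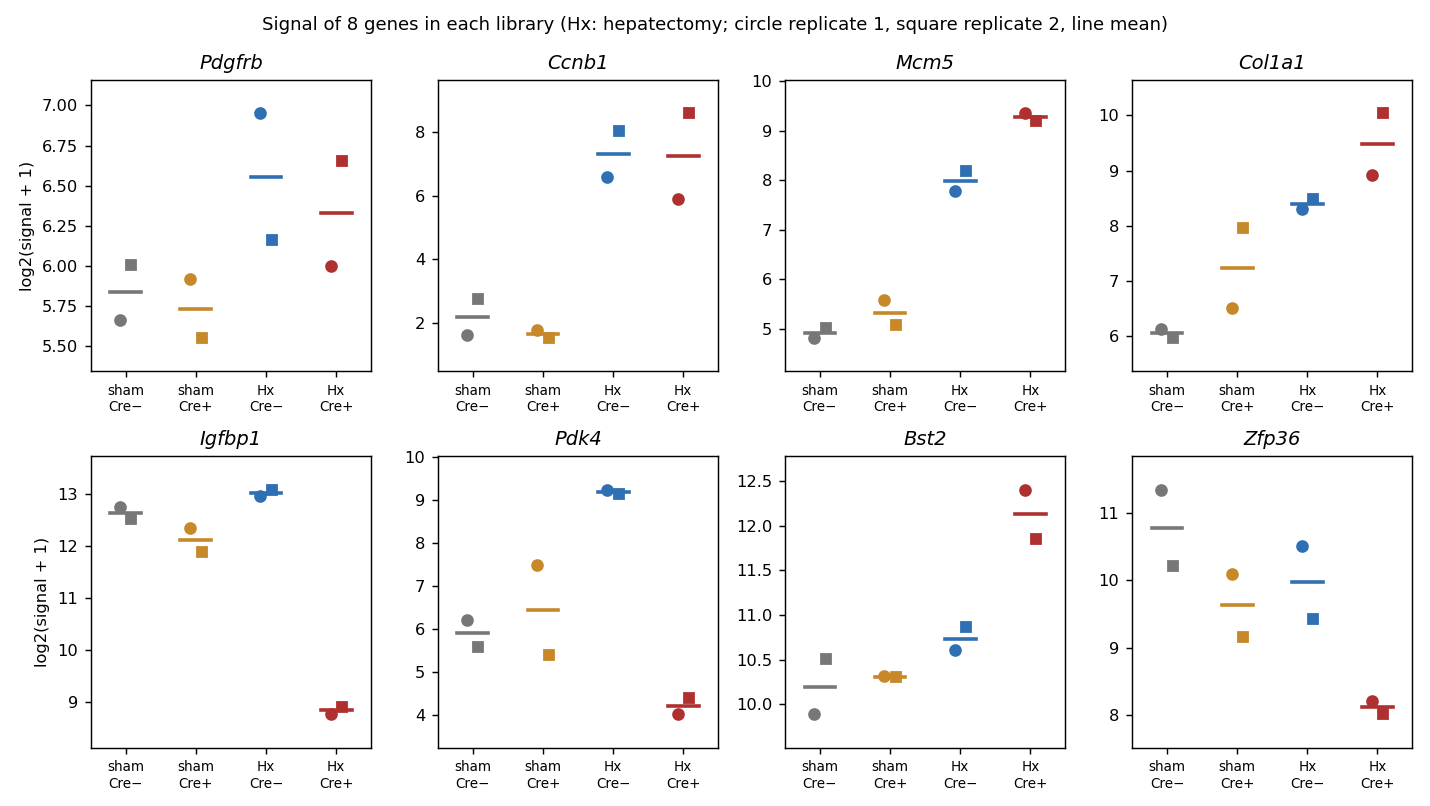
log2(signal + 1) of 8 genes (vertical axis) in each group (horizontal axis), with a circle for replicate 1, a square for replicate 2 and a line at the group mean. Ccnb1 and Mcm5 lie higher in every hepatectomy library than in every sham library, and Igfbp1 lies at 436.5 and 480.3 signal units in the Cre-positive hepatectomy libraries.

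Averaged over genotypes, hepatectomy set 4 libraries against 4 and gave the largest number of calls. Cdc20, the activator of the anaphase complex, rose by 6.04 (SE 0.79, adjusted p = 0.00983), Ccnb1 by 5.34 (SE 0.64, adjusted p = 0.00736) and Mcm2 by 2.78 (SE 0.21). All 40 mitosis genes rose, both over all genes and adjusted over the list alone (median 4.19). Of 29 replication genes 21 rose over all genes, and 25 rose and 1 fell adjusted over the list alone (median 1.85). Of 25 G1 cyclins, CDK inhibitors and growth arrest genes 6 rose, and adjusted over the list alone 6 rose and 1 fell. Cdkn1a, the CDK inhibitor p21, rose by 2.31 (SE 0.37, adjusted p = 0.0197) and Ccne1, cyclin E1, by 1.53 (SE 0.25, adjusted p = 0.0221). Camera gave adjusted p = 7.76e-35, 4.15e-18 and 0.0382 for these lists, or adjusted p = 0.2, adjusted p = 0.182 and adjusted p = 0.299 with an estimated correlation. The G1 call was lost without Cre-negative sham replicate 2 (0.0857), Cre-positive sham replicate 2 (0.0556), Cre-negative hepatectomy replicate 1 (0.0863) or 2 (0.0551), or Cre-positive hepatectomy replicate 1 (0.209).

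Some matrix genes rose in this contrast. Col1a1 and Col3a1, the fibrillar collagens of type I and III, rose by 2.30 (SE 0.38, adjusted p = 0.022) and 1.14 (SE 0.22, adjusted p = 0.0347). Vim, the intermediate filament vimentin, rose by 1.10 (SE 0.21, adjusted p = 0.0349). Of the 34 fibrillar matrix and myofibroblast genes 30 had positive fold changes (median 0.80), 5 rose over all genes and 6 adjusted over the list alone (camera adjusted p = 0.000104, and adjusted p = 0.528 with an estimated correlation). Col4a1 and Col4a2, collagens of the basement membrane, rose by 0.94 (SE 0.19, adjusted p = 0.0412) and 0.97 (SE 0.20, adjusted p = 0.0446), while that list of 13 did not pass (adjusted p = 0.66). Stellate cell markers did not move together. Colec10, a collectin, fell by 2.31 (SE 0.44, adjusted p = 0.0343). The list of 22 had a median of -0.21, with 1 rising and 6 falling adjusted over the list alone. Its camera adjusted p of 0.0357 became adjusted p = 0.528 with an estimated correlation. It missed the threshold without Cre-negative sham replicate 2 (0.0536), Cre-positive sham replicate 1 (0.079), Cre-negative hepatectomy replicate 1 (0.0938) or Cre-positive hepatectomy replicate 1 (0.209), and with median-of-ratios scaling (0.0511). Endothelial markers fell on balance (median -0.46, camera adjusted p = 1.81e-05, and adjusted p = 0.528 with an estimated correlation). Of 27, 3 fell over all genes and 7 adjusted over the list alone, among them Kdr, a receptor for vascular endothelial growth factor, by 1.13 (SE 0.23, adjusted p = 0.0413) and Oit3 by 1.31 (SE 0.21, adjusted p = 0.022).

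Some genes of the hepatocyte lists fell. Glul fell by 1.42 (SE 0.15, adjusted p = 0.00452), Cyp2e1, an ethanol-oxidizing P450, by 1.60 (adjusted p = 0.0108) and Cyp1a2 by 1.02 (SE 0.17, adjusted p = 0.0229). In total 5 of the 14 pericentral genes fell over all genes and 5 adjusted over the list alone (median -0.56, camera adjusted p = 2.91e-05). Of the 18 periportal genes 3 fell over all genes, and adjusted over the list alone 9 fell and 1 rose (median -0.65, 0.000108), including Cyp2f2 by 1.28 (adjusted p = 0.0354) and Pigr by 1.39 (SE 0.23, adjusted p = 0.022). Slc10a1, the sodium-dependent bile acid importer, fell by 1.17 (SE 0.23, adjusted p = 0.0398). In its list 3 of 20 bile acid genes fell and 1 rose over all genes, or 4 fell and 1 rose adjusted over the list alone (median -0.62, 2.56e-05). Among 22 P450 genes 5 fell and 1 rose over all genes, and 11 fell and 1 rose adjusted over the list alone (median -0.62, 5.21e-08). Of 14 male-biased genes 5 fell over all genes and 10 adjusted over the list alone (median -1.71, 1.88e-06). By contrast 4 of the 18 female-biased genes rose, among them Cyp3a16 by 2.99 and Cyp3a44 by 2.68 (adjusted p = 0.0102 and 0.0181). That list had 7 rising and 4 falling adjusted over the list alone and no call by camera (0.0808). For the periportal list this was adjusted p = 0.299 with an estimated correlation, and for the pericentral, bile acid, P450 and male-biased lists adjusted p = 0.2 with an estimated correlation.

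Further lists passed camera in the averaged contrast. Ribosomal protein genes were higher (8 of 81 over all genes and 34 adjusted over the list alone, median 0.45, adjusted p = 1.06e-09). Rpl41 rose by 1.23 (SE 0.15, adjusted p = 0.00801) and Rplp1 by 1.00 (SE 0.16, adjusted p = 0.0188). Fetal liver genes were higher, 3 of 7 over all genes and 5 adjusted over the list alone (median 1.99, adjusted p = 0.00942, 0.0516 without Cre-positive hepatectomy replicate 1). Afp, alpha-fetoprotein, rose by 2.02 (SE 0.43, adjusted p = 0.0462) and the noncoding RNA H19 by 2.52 (SE 0.50, adjusted p = 0.0403). Fatty acid synthesis genes were lower (3 of 18 over all genes and 3 adjusted over the list alone, median -0.22, adjusted p = 0.0181, 0.174 without Cre-positive hepatectomy replicate 1 and 0.253 with quantile normalization). Pklr fell by 1.67 (SE 0.18, adjusted p = 0.00509). Clock genes were lower (1 of 17 over all genes and 1 adjusted over the list alone, Bhlhe40, median -0.40, adjusted p = 0.0167), but not without Cre-negative hepatectomy replicate 2 (0.0666) or Cre-positive hepatectomy replicate 2 (0.0527), nor with quantile normalization (0.0729). All of these had adjusted p = 0.2 with an estimated correlation. Cholangiocyte and progenitor markers (median 0.74, adjusted p = 0.0167, 0.0596 without Cre-negative hepatectomy replicate 1) and the interferon list (24 of 26 positive, median 0.89, adjusted p = 0.002, 0.418 without Cre-positive hepatectomy replicate 1) were higher, with adjusted p = 0.528 and adjusted p = 0.67 with an estimated correlation. After hepatectomy, cholangiocyte markers and fetal liver genes were lower and interferon genes higher in Cre-positive than in Cre-negative livers. The averages of these lists therefore do not show a rise in each genotype. The Y-linked genes, with 4 members measured, had a median of -1.15 and adjusted p = 0.0382, or adjusted p = 0.528 with an estimated correlation. The lowest values were in Cre-positive hepatectomy replicate 2, where Ddx3y was at 8.08 against 530.5, 410.5 and 450.5 in the other hepatectomy libraries, and without that library the adjusted p was 0.0226. Without Cre-negative hepatectomy replicate 1 or 2 it was 0.05 or 0.112, with median-of-ratios scaling 0.0888, with quantile normalization 0.0729 and with the GC correction, chosen after the data were seen, 0.0504.

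Other lists did not pass camera for hepatectomy averaged over genotypes. The adjusted p was 0.0617 for growth factors and receptors of regeneration, for immediate early genes and for acute phase genes, 0.063 for ERK target and feedback genes, 0.0722 for erythroid genes, 0.0759 for mitochondrially encoded genes and 0.144 for hepatocyte secreted proteins. The mitochondrial result is uncertain, since mt-Atp6, mt-Atp8, mt-Co1 and mt-Co3 were listed at 0 in 3 libraries. These were Cre-positive sham replicate 2, Cre-negative hepatectomy replicate 1 and Cre-positive hepatectomy replicate 1. Skeletal muscle, pancreatic acinar and adipocyte lists had 0.563, 0.655 and 0.758. With only 1, 2 and 4 genes tested of 9, 15 and 7 entries, they cannot speak for a cell type. The adjusted p was 0.153 for cholesterol synthesis, 0.401 for infiltrating myeloid cells, 0.409 for Kupffer cells, 0.655 for PPAR-alpha targets and 0.888 for lymphocytes. It was 0.925 for PDGF ligands and the other PDGF receptor, for unfolded protein response genes and for mesothelium. Single members still passed in some of these. Cyp4a14 rose by 2.87 (SE 0.47, adjusted p = 0.0227) and Slc4a1, the anion exchanger of red cells, by 3.45 (SE 0.64, adjusted p = 0.0331). Igfbp1 fell by 1.45 (SE 0.17, adjusted p = 0.00711) and Spry4, a feedback inhibitor of ERK signalling, by 1.77 (SE 0.27, adjusted p = 0.0178). The genotypes did not move alike in Cyp4a14 and Igfbp1. Cyp4a14 was at 99.97 and 55.99 in Cre-positive sham and 71.6 and 111.7 in Cre-positive hepatectomy libraries. Its averaged rise came from Cre-negative livers. Igfbp1 was at 6883.2 and 5838 in Cre-negative sham and 7883.4 and 8615.3 in Cre-negative hepatectomy libraries. Its averaged fall came from Cre-positive livers. Pdgfrb itself had a log2 fold change of 0.66 (SE 0.27) and did not pass (adjusted p = 0.204).

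**Figure D3:**
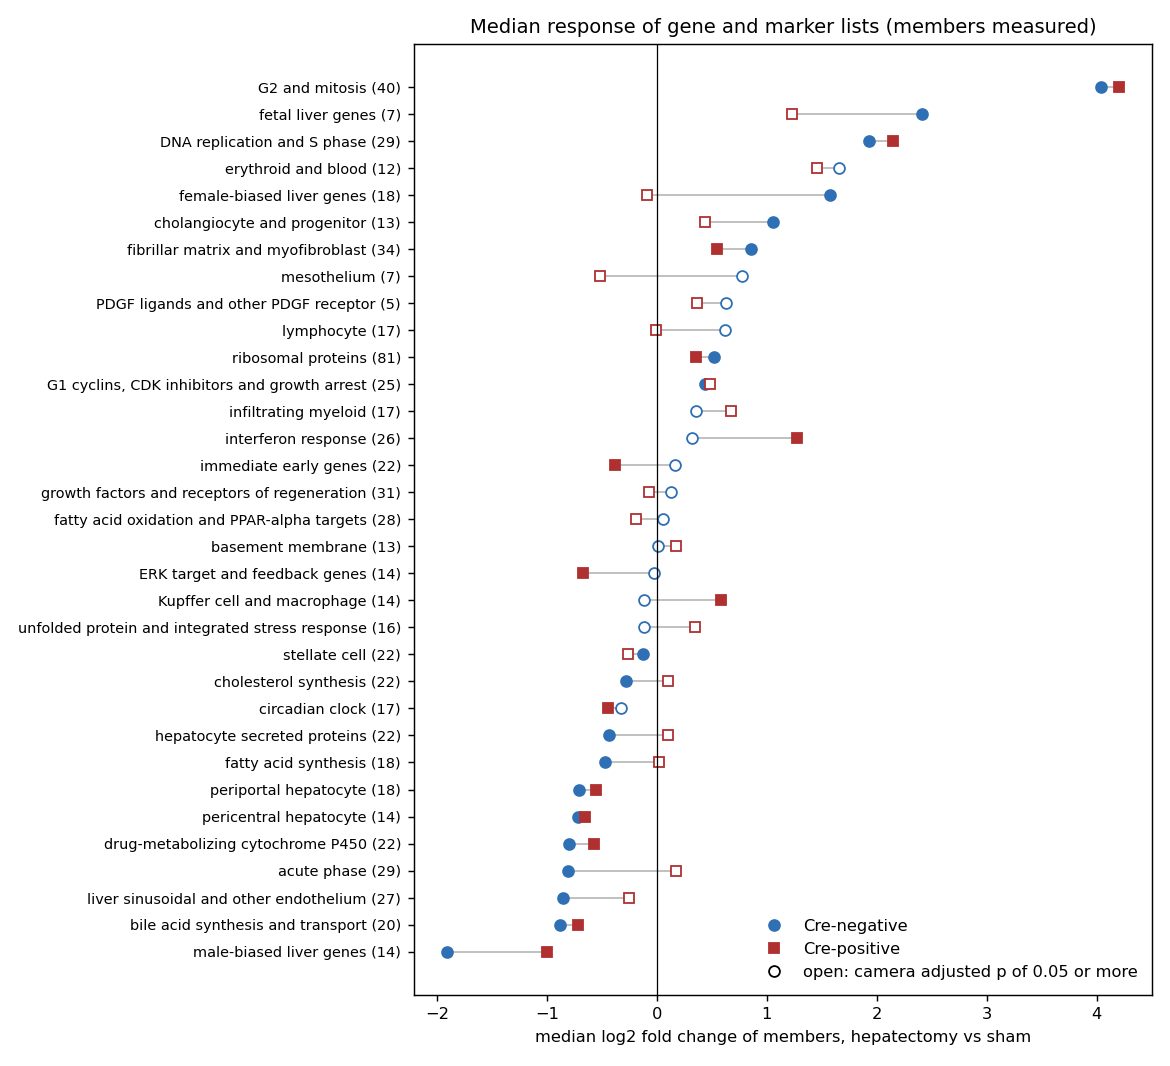
Median log2 fold change of hepatectomy against sham (horizontal axis) for gene lists of at least 5 members (vertical axis), with the list of mitochondrially encoded genes left out. Circles stand for Cre-negative and squares for Cre-positive livers, filled where the camera adjusted p at the preset correlation was under 0.05. The G2 and mitosis list lies farthest to the right, at 4.04 and 4.2.

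Over both genotypes 599 genes rose and 139 fell, with 3917 at an unadjusted p under 0.05. The total of 738 was 149, 189, 140 and 188 without Cre-negative sham replicate 1 or 2 or Cre-positive sham replicate 1 or 2. It was 248 and 431 without Cre-negative hepatectomy replicate 1 or 2, and 5408 without Cre-positive hepatectomy replicate 1, of which 3060 rose and 2348 fell.

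In sham livers, labelled Cre-positive against Cre-negative, genes that respond within minutes to stimulation were lower as a group. All 22 immediate early genes had negative log2 fold changes, with a median of -0.93 (camera adjusted p = 3.64e-15, and adjusted p = 0.649 with an estimated correlation). No single member passed by limma, over all genes or adjusted over the list alone, although 2 had an unadjusted p under 0.05. The mRNA-destabilizing factor Zfp36 was at 2596 and 1189 in Cre-negative and 1091 and 573 in Cre-positive sham libraries, and the cytokine feedback gene Socs3 at 1297 and 735 against 785 and 135. Growth factors and receptors were lower as a list (median -0.31, adjusted p = 0.000198, 0.0671 without Cre-negative sham replicate 1 and 0.0741 without Cre-positive sham replicate 2). So were cholangiocyte markers (1 of 13 positive, median -0.42, adjusted p = 0.00336, 0.577 without Cre-negative sham replicate 1, 0.0564 and 0.063 without Cre-positive hepatectomy replicate 1 or 2). PPAR-alpha targets were higher (22 of 28 positive, median 0.09, adjusted p = 4.48e-05, 0.23 without Cre-negative sham replicate 2). These 3 lists had adjusted p = 0.649 with an estimated correlation, and the lowest adjusted p of fry was 0.964.

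A single gene passed between the sham groups, AL845466.1, a clone-named gene outside the rule for named genes and given because it was the only call. It was at 2.07e-05 and 0.00077 in the Cre-negative and at 2049.7 and 621.7 in the Cre-positive sham libraries (adjusted p = 0.00498). Its signal in the hepatectomy libraries was at most 0.00206. Its value of 621.72 in Cre-positive sham replicate 2 recurred in another gene, Snord118, in Cre-negative hepatectomy replicate 1. That small RNA gene was chosen after its value was seen, and why the value recurs was not tested. Among genes that did not pass, Sgk1, a kinase induced by glucocorticoids, went from 1363 and 1409 to 622.3 and 469.0 (log2 fold change -1.36, SE 0.23, adjusted p = 1). Serpina1e went from 64447 and 67295 to 9343 and 10867 (-2.71, SE 0.49, adjusted p = 1). At an unadjusted p under 0.05 there were 146 genes, against 822 if p-values were uniform, and the shared spread is wider than that between sham replicates. In the simulation with the observed spreads and independent genes, 0.8% of unchanged genes had such a p in this contrast. Against that share the 146 are not few, but the share may differ where genes vary together. The count was 0 without Cre-negative sham replicate 2 (139 at an unadjusted p under 0.05), Cre-negative hepatectomy replicate 1 (184) or replicate 2 (195), 4 without Cre-positive sham replicate 2, and 19 without Cre-positive hepatectomy replicate 1 or 2. It was 1 without Cre-negative sham replicate 1 or with only the sham groups in the fit, but each time another gene, with AL845466.1 at adjusted p = 0.0681 and 0.0775.

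After hepatectomy, livers labelled Cre-positive differed from Cre-negative livers most clearly in Igfbp1. Igfbp1 was at 7883.4 and 8615.3 in Cre-negative and 436.5 and 480.3 in Cre-positive libraries, a log2 fold change of -4.17 (SE 0.24, adjusted p = 0.00668, n = 2). Cbx8, a Polycomb protein, rose from 15.4 and 13.2 to 249.8 and 284.8 (log2 fold change 4.14, adjusted p = 0.0177). The small Cajal body RNA SCARNA4, outside the rule for named genes and given because it was among the 3 calls, was at 47.4 and 52.2 in Cre-negative libraries and listed at 0 in both Cre-positive libraries (adjusted p = 0.00686). Genes that did not pass included Pdk4, the pyruvate dehydrogenase kinase of fasting, at 606.6 and 566.4 against 15.3 and 20.2 (log2 fold change -4.98, SE 0.63, adjusted p = 0.0888). They also included the lectin Lgals4 at 563.4 and 414.3 against 70.1 and 82.0 (-2.66, SE 0.32, adjusted p = 0.0888), and Tff3 at 129 and 138 against 15.6 and 29.2 (-2.59, adjusted p = 0.0988).

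Lists moved in this contrast without a member past the threshold over all genes by limma. Of the 18 lists that passed camera here, 1 also passed fry. Interferon genes were higher in 25 of 26 cases (median 1.30, camera adjusted p = 2.24e-09), with 10 at an unadjusted p under 0.05 and 6 rising adjusted over the list alone. Bst2 was at 1555 and 1859 in Cre-negative against 5414 and 3699 in Cre-positive libraries. Kupffer cell and macrophage markers were higher in 13 of 14 cases (median 0.75, adjusted p = 1.91e-07, 7 at an unadjusted p under 0.05, 5 rising adjusted over the list alone). Cd5l, a protein secreted by macrophages, was at 426 and 405 against 1420 and 1166. Acute phase genes were higher in 23 of 29 (median 0.78, adjusted p = 1.91e-07), replication genes in 24 of 29 (0.51, 1.01e-06) and male-biased genes in 12 of 14 (0.91, 1.26e-05). These had 12, 7 and 4 members at an unadjusted p under 0.05 and 0, 0 and 4 rising adjusted over the list alone. All 22 immediate early genes were lower (median -1.66, adjusted p = 5.94e-05), 10 at an unadjusted p under 0.05 and 7 falling adjusted over the list alone. Zfp36 was at 1457 and 690 against 296 and 258. All 7 fetal liver genes were lower (median -1.56, adjusted p = 0.00849), 3 at an unadjusted p under 0.05 and 1 falling adjusted over the list alone. So were 12 of 13 cholangiocyte markers (median -1.08, adjusted p = 0.00734), 6 at an unadjusted p under 0.05 and 3 falling adjusted over the list alone. With an estimated correlation the Kupffer cell, acute phase, replication, male-biased and fetal lists had adjusted p = 0.517, and the interferon, immediate early and cholangiocyte lists adjusted p = 0.556 with an estimated correlation. Without Cre-positive hepatectomy replicate 1 the interferon (0.0782), immediate early (0.0858), cholangiocyte (0.215) and fetal (0.0787) lists missed the threshold, the fetal list also without Cre-positive hepatectomy replicate 2 (0.0573). Of the 18 lists that passed, 4 passed with each library left out in turn, namely replication, male-biased, acute phase and Kupffer cell genes. Hepatocyte secreted proteins passed upward (adjusted p = 0.0042, and adjusted p = 0.556 with an estimated correlation) with a positive median of 0.23 and a negative mean of -1.01. The call was lost without Cre-positive hepatectomy replicate 1 (0.135), in which Trf, the transferrin gene, was listed at 0, with quantile normalization (0.508) and with the GC correction, chosen after the data were seen (0.0555). The G2 and mitosis list did not differ by camera (adjusted p = 0.946). It passed in one direction without Cre-negative hepatectomy replicate 1 (0.00136) or Cre-positive hepatectomy replicate 2 (0.0216), and in the other without Cre-negative hepatectomy replicate 2 (0.0302) or Cre-positive hepatectomy replicate 1 (0.0281).

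The GC trend of Cre-positive hepatectomy replicate 2, at -1.5 for genes under 40% GC, lies on one side of this contrast, and the replicates of each hepatectomy group differed more than sham replicates. By limma 1 gene rose and 2 fell, with 3009 at an unadjusted p under 0.05. In the simulation with the observed spreads and independent genes, 11.7% of unchanged genes had such a p in this contrast. The total of 3 was 0 without Cre-negative sham replicate 1 or 2 (2192 and 2190 at an unadjusted p under 0.05). Without Cre-positive sham replicate 1 or 2 it was 3 each time, with 2 of the 3 kept and Cbx8 lost (adjusted p = 0.0998 and 0.0943). It was 1 without Cre-negative hepatectomy replicate 1, with 0 of the 3 kept, and 90, 2217 and 63 without Cre-negative hepatectomy replicate 2 or Cre-positive hepatectomy replicate 1 or 2. With only the hepatectomy groups in the fit it was 0 (1241 at an unadjusted p under 0.05).

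Whether the response to hepatectomy differed between genotypes was tested as the difference of both fold changes. By limma 2 genes passed, SCARNA4 and AL845466.1 (adjusted p = 0.0285 each), both outside the rule for named genes and given because they were the only calls. SCARNA4 was at 18.6 and 19.02 in Cre-negative sham and 57.2 and 34.3 in Cre-positive sham libraries. After hepatectomy it was at 47.4 and 52.2 in Cre-negative libraries and listed at 0 in both Cre-positive libraries. Igfbp1 did not pass, with a difference of -3.65 on the log2 scale (adjusted p = 0.0631). Neither did Cbx8 with 4.23 (SE 0.46, adjusted p = 0.122), Serpina1e with 4.79 (adjusted p = 0.21) or Pdgfrb with -0.13 (SE 0.55, adjusted p = 0.955). Camera placed the interferon (adjusted p = 8.71e-07), Kupffer cell (1.91e-05), male-biased (1.91e-05), acute phase (4.41e-05) and replication (6.31e-05) lists above other genes in this difference. These had 6, 4, 3, 2 and 3 members at an unadjusted p under 0.05 and 0 past the threshold over all genes by limma. Adjusted over the list alone, 2 male-biased genes passed and 0 of the others. For the male-biased and replication lists this was adjusted p = 0.497, for acute phase genes adjusted p = 0.587, and for the interferon and Kupffer cell lists adjusted p = 0.736, each with an estimated correlation. The interferon list had adjusted p = 0.201 without Cre-positive hepatectomy replicate 1, and the acute phase list 0.0575 with quantile normalization. The library with the GC trend, in which genes under 40% GC were at -1.5, enters this difference on one side.

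The count of 2 for the difference of responses was 0 without Cre-negative sham replicate 1 or 2 (681 and 647 at an unadjusted p under 0.05), Cre-positive sham replicate 1 (713) or Cre-negative hepatectomy replicate 1 (806), and 771 and 48 without Cre-positive hepatectomy replicate 1 or 2. It was 3 without Cre-negative hepatectomy replicate 2, with 0 of the 2 kept, and 2 without Cre-positive sham replicate 2, with 1 kept. The SE had a median of 0.587 in this contrast against 0.415 in those between a pair of groups, and 1330 genes had an unadjusted p under 0.05.

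Averaged over treatments, livers labelled Cre-positive had lower Igfbp1, with a log2 fold change of -2.34 (SE 0.17, adjusted p = 0.0286), and AL845466.1, outside the rule for named genes, was the only other gene to pass (adjusted p = 0.0286). Immediate early genes were lower in 22 of 22 cases (median -1.43, camera adjusted p = 1.07e-09), with 0 falling over all genes by limma, 12 at an unadjusted p under 0.05 and 11 adjusted over the list alone. Kupffer cell markers were higher in 14 of 14 (median 0.46, adjusted p = 1.72e-08), with 0 over all genes, 5 at an unadjusted p under 0.05 and 5 adjusted over the list alone, and acute phase genes in 24 of 29 (0.48, 1.99e-08). All of these had adjusted p = 0.459 with an estimated correlation. Of the 19 lists that passed camera in this contrast, 1 also passed fry. Pdgfrb had a log2 fold change of -0.16 (SE 0.27, adjusted p = 0.85). There were 1402 genes at an unadjusted p under 0.05. The count of 2 was 0 without Cre-negative sham replicate 1 or 2 (693 and 789), Cre-positive sham replicate 1 (778) or Cre-negative hepatectomy replicate 1 (811), and 971 and 21 without Cre-positive hepatectomy replicate 1 or 2. It was 2 without Cre-positive sham replicate 2 or Cre-negative hepatectomy replicate 2, with 1 and 0 of the 2 kept, and Igfbp1 did not pass in either (adjusted p = 0.0949 and 0.0926).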

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

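No test in this part was chosen after the result was seen, apart from the GC content correction: each result comes from the test of the difference in the response to hepatectomy between the genotypes, and is given because that difference passed. For 2 genes it passed by limma. AL845466.1 (adjusted p = 0.0285) was at 2049.7 and 621.7 in the Cre-positive sham libraries and at 0.00206 or less in the other libraries. SCARNA4 (adjusted p = 0.0285) was at 47.4 and 52.2 in the Cre-negative hepatectomy libraries and listed at 0 in both Cre-positive hepatectomy libraries. Neither passed without Cre-negative sham replicate 1 or 2, Cre-positive sham replicate 1, or Cre-negative hepatectomy replicate 1 or 2, and SCARNA4 did not without Cre-positive sham replicate 2 (0.0605). Both were named after their values were seen, and in values of this kind an exact 0 can be a failed estimate.

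For 11 gene lists the difference passed by camera at the preset correlation, and for 0 with an estimated correlation. Relative to other genes, the response of the interferon list (adjusted p = 8.71e-07, median difference 1.06), of Kupffer cell and macrophage markers (1.91e-05, 0.81) and of endothelial markers (0.000324, 0.44) was more positive in the livers labelled Cre-positive. These had adjusted p = 0.736 with an estimated correlation. So was that of male-biased genes (1.91e-05, 0.93), replication and S phase genes (6.31e-05, 0.62) and fatty acid synthesis (0.018, 0.33), with adjusted p = 0.497 with an estimated correlation, and of acute phase genes (4.41e-05, 0.68), with adjusted p = 0.587 with an estimated correlation. Periportal genes (0.0388, 0.42), drug-metabolizing cytochromes P450 (0.0434, 0.32) and hepatocyte secreted proteins (0.00859) passed in the same direction, the last with a positive median of 0.45 and a negative mean of -0.30, and all had adjusted p = 0.736 with an estimated correlation. Fetal liver genes passed in the other direction (0.0322, median -1.42, adjusted p = 0.497 with an estimated correlation), and of the 38 lists 1, this list, passed fry (adjusted p = 0.0264).

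Replication, male-biased, acute phase and Kupffer cell genes passed with each library left out in turn, and the other 7 lists did not. Without Cre-positive hepatectomy replicate 1 the adjusted p was 0.201 for interferon genes, 0.188 for secreted proteins, 0.27 for periportal and P450 genes, 0.146 for fetal genes and 0.0776 for fatty acid synthesis. Without replicate 2 of that group it was 0.059 for periportal genes and fatty acid synthesis and 0.103 for fetal genes. Without Cre-negative hepatectomy replicate 2 it was 0.354 for endothelial markers and 0.0795 for fatty acid synthesis. For periportal and P450 genes it was 0.322 and 0.316 without Cre-negative hepatectomy replicate 1, 0.173 and 0.644 without Cre-negative sham replicate 1, and 0.0831 and 0.0723 without Cre-positive sham replicate 1. Quantile normalization gave 0.854 for both, 0.594 for secreted proteins, 0.302 for fatty acid synthesis and 0.0575 for acute phase and fetal genes. Median-of-ratios scaling gave 0.0826 for periportal and 0.0674 for P450 genes, a pseudocount of 0.1 gave 0.0503 for fetal genes, and the GC correction gave 0.14 for periportal genes and 0.0949 for secreted proteins.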

How the results depend on the processing

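Leaving out the 105 genes listed at 0 in a library and abundant in another, array weights and the GC content correction were chosen only after the data had been seen, and the other settings before. Counts of genes past the threshold stayed within 1.5 times in 62 cases, moved further in 52 and fell to 0 in 23. No named gene reversed: 2524 values kept their side of the threshold, 1075 no longer passed and 60 passed only in the other setting. Pdgfrb stayed on its side of the threshold in all 137 values, and its sign changed in 12. The cause was not tested where none is stated.

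Hepatectomy in Cre-negative livers gave 183 genes, and 103 with no filter, 77 with median-of-ratios scaling, 79 with quantile normalization, 63 with only the groups compared, 284 without the 105 genes, 813 with array weights and 440 with the GC correction. The last split was 315 up and 125 down against 166 and 17. In Cre-positive livers 155 genes became 7 with no filter, 99 with quantile normalization, 0 with only the groups compared, 0 with array weights and 237 with the GC correction. Averaged over genotypes 738 genes became 405 with no filter and 422 with array weights, and the GC correction gave 687 up and 369 down against 599 and 139. For genotype in sham livers 1 gene became 0 with no filter (356 at an unadjusted p under 0.05 by limma), 0 without the 105 genes, of which it is one (146), and 33 with array weights. For genotype after hepatectomy 3 genes became 22 with no filter, 0 with only the groups compared, 7 with no intensity trend and 0 with array weights, while the scalings and the GC correction kept all 3. For the difference of responses 2 genes became 1 of the 2 with a pseudocount of 0.1 and without the 105 genes, 1 other gene with no filter, and 0 with array weights. For genotype averaged over treatments 2 became 7 with no filter, 0 with no intensity trend (1476), 1 without the 105 genes and 0 with array weights. At an unadjusted p under 0.05 the zeros of array weights had 1399, 989, 905 and 1000 genes in the order given, and those of only the groups compared 1493 and 1241. With array weights the sham libraries weighed 2.49 or more and the Cre-positive hepatectomy libraries 0.247.

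With 1 library left out, its group held 1 library, which was assumed to vary like the other groups. Counts then lay between 0 and 1698 for hepatectomy in Cre-negative livers, 1 and 3507 in Cre-positive livers and 140 and 5408 averaged over both. They lay between 0 and 19 for genotype in sham, 0 and 2217 after hepatectomy, 0 and 971 averaged over treatments, and 0 and 771 for the difference of responses. Each maximum came without Cre-positive hepatectomy replicate 1, for genotype in sham also without replicate 2. That group had the widest spread between replicates, with a median ratio of 1.606, and leaving out 1 of its libraries takes that spread out of the fit. Without replicate 1 the group was replicate 2 alone, the library with the GC trend. The maxima are therefore no support for the main calls. At an unadjusted p under 0.05 the zeros had 1745 genes for hepatectomy in Cre-negative livers, 139 to 195 for genotype in sham, 2190 and 2192 after hepatectomy, 693 to 811 averaged and 647 to 806 for the difference. Of 34 named calls in Cre-negative livers 0 passed without Cre-negative sham replicate 1, of 33 in Cre-positive livers 0 without Cre-positive sham replicate 1, and of 82 averaged over both 28 and 27 without these libraries.

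Of the list results 3708 stayed on their side of the threshold, 403 no longer passed, 141 passed only in the other setting and 4 reversed. The P450 list in sham livers, not called at 0.889, was called the other way without Cre-negative sham replicate 1 (0.000674), with a range of 0.000591 to 0.962 over the left-out libraries. Cholesterol synthesis there was called the other way without Cre-positive sham replicate 2 (0.028, range 0.00288 to 0.795). G2 and mitosis genes after hepatectomy were called the other way without Cre-negative hepatectomy replicate 1 (0.00136) or Cre-positive hepatectomy replicate 2 (0.0216), with a range of 0.00136 to 0.964. No paired analysis was possible because the labels give no replicate numbers that groups share. Tests on read counts were not run, because whole reads could not be recovered, and the unknown depth leaves the precision of low signals open.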

Other observations

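The tests of explanations for the Y-linked, clock and Igfbp1 patterns were chosen only after the results they bear on had been seen, and the tests of gene lists and the counts over other splits before.

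After hepatectomy, several smaller groups of genes also differed between the genotypes. Genes of the unfolded protein response lay above other genes in livers labelled Cre-positive (median 0.20, camera adjusted p = 0.0253, and adjusted p = 0.517 with an estimated correlation). By limma 0 of 16 rose over all genes, 5 were higher at an unadjusted p under 0.05 and 4 rose adjusted over the list alone, with the chaperone Calr at 2476 and 3259 in Cre-negative and 6012 and 7644 in Cre-positive libraries. The call was lost without Cre-negative hepatectomy replicate 2 (0.202), Cre-positive hepatectomy replicate 1 (0.114) or replicate 2 (0.052), and with quantile normalization (0.282). All 7 mesothelial markers were lower (median -1.13, adjusted p = 0.0209, and adjusted p = 0.556 with an estimated correlation), with Msln, mesothelin, at 122.3 and 234.8 against 34.9 and 60.9. By limma 0 of them fell over all genes, 3 were lower at an unadjusted p under 0.05 and 1 fell adjusted over the list alone. That call was lost without Cre-negative hepatectomy replicate 2 (0.3) or Cre-positive hepatectomy replicate 1 (0.249), and with quantile normalization (0.0922). The lists of PPAR-alpha targets (camera adjusted p = 0.487) and female-biased genes (0.16) did not pass, while 6 of 28 and 4 of 18 members fell adjusted over the list alone. Hpx, the heme-binding plasma protein hemopexin, was at 101040 and 130020 against 341080 and 1452200 without passing (adjusted p = 0.146).

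Other splits of the libraries were counted in a limma fit with a mean for each side and no term for the other factor. Hepatectomy against sham gave 815 genes, and of the 35 splits into 4 and 4 libraries this 1 gave as many, with 2 as the highest of the others. This argues against a chance split of these libraries, though 1 in 35 is the lowest share the test can give. It cannot tell hepatectomy from anything else that the hepatectomy libraries share. Cre-positive against Cre-negative gave 0 genes (557 at an unadjusted p under 0.05), and with a count of 0 every one of the 35 splits gives as many, so this count says nothing about chance. The highest other split, with 815, is hepatectomy against sham, the main structure of these samples.

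Y-linked genes were low in Cre-positive hepatectomy replicate 2, in which Ddx3y was at 8.08 against 410.5 or more in every other library, and Eif2s3y, Kdm5d and Uty were at 54.1, 38.5 and 19.7. A female animal is argued against by Xist, the RNA of X inactivation, which was at 0.0376 there and between 0.019 and 0.91 in the other libraries. The GC trend of the library may account for part of the pattern: among genes matched on GC content, length and level, the Y-linked genes had a median percentile of 14.9. It stays open, because Ddx3y lay at a log2 deviation of -5.93, below all 19 of its matched genes (median -2.08), while Eif2s3y, Uty and Kdm5d lay at percentiles of 8.7, 21.1 and 44 of theirs, and the X-linked Ddx3x was low too, at 171 against 1275 or more elsewhere. The design names no biological difference between these replicates, and no biological explanation other than a female animal was tested.

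Clock genes differed between the replicates of both hepatectomy groups. Arntl was at 26.8 and 122.2 in Cre-negative and 11.8 and 148.7 in Cre-positive libraries, Dbp at 480 and 108 and at 312 and 21.6, and 12 of 17 clock genes had differences of the same sign. Replicate numbers are not shared between groups, so the sign of that agreement is arbitrary. Collection of the animals at different times of day could give this, and stays open: the correlation of the replicate differences between the groups was 0.544, against a 95th percentile of 0.557 in 10000 random lists matched on level. After GC correction the correlation was 0.734 against a 95th percentile of 0.598. This cannot decide on the GC trend as a cause. Over all genes the replicate differences of the groups correlated at only -0.041 before the correction, so the trend was not shared between the groups. The labels used here give no time of collection, and no biological explanation was tested.

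Igfbp1 and 6 PPAR-alpha targets picked for their values (Acot1, Acot2, Cyp4a10, Cyp4a14, Pdk4 and Ppargc1a) were lower in the Cre-positive hepatectomy livers, with a median log2 fold change of -3.03. The GC trend is argued against as the whole cause, since after GC correction the median was -2.91 and Igfbp1 still passed (-4.11, adjusted p = 0.00527). Different collection times stay open: the larger replicate difference had a median of 1.02 on the log2 scale, but the genes were picked by a test that favours a small spread, and for 3 of the 7 it was at least 0.5 of the change. A difference in feeding state may account for the pattern and stays open too: fatty acid synthesis genes, which feeding raises, lay above other genes in these livers without passing (camera adjusted p = 0.0695), with 4 members higher and 3 lower at an unadjusted p under 0.05. The genotype stays open and untested apart from the contrast itself. There a simulation with the observed spread of each group and independent genes called 22 unchanged genes.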
